A study of Mus musculus with 2 samples.

How the data were processed

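Retinas of wild-type mouse embryos at E15.5 were dissociated, sorted and profiled as single cells with the 10x Chromium 3' v2 chemistry, in which each cDNA molecule carries a cell barcode and a unique molecular identifier (UMI). Per the labels' protocols, 30 retinas were used, 7000 cells were loaded per channel, and the read lengths were 26 and 98 bp. The study holds 2 libraries of 1 group. The deposited table names its cells by 2 lanes, and no label ties a lane to a library, so all cells were used as 1 pooled sample. Values of lane 1 and lane 2 are given beside the pooled value, and the lanes are not used as replicates here.

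The authors deposited UMI counts per gene and cell, merged in 1 table of 5347 cells and 15176 genes. The submitters' processing notes name Cell Ranger 2.1.1, Seurat 2.3, R 3.4.4 and the build mm10, without saying which step each served. The filters on cells are not given in the sources used here. Every deposited gene had a UMI in at least 3 cells. The authors also deposited a natural log table, which equalled ln(1 + 10000 × count / cell total) of the counts to within 1e-06; it was used to check the counts and to restore 13 gene symbols. A table scaled per gene was not used here.

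Lane 1 held 11579803 UMIs in 2673 cells, and lane 2 held 12390435 UMIs in 2674 cells. The labels state 2675 and 2673 cells for the libraries and 5347 for the series. Of all barcodes, 13 occurred in both lanes. No cell filter was applied for the values reported. Scrublet, as implemented in scanpy 1.11.5, was run per lane with an expected doublet share of 2% and marked 26 cells of lane 1 (0.973%) and 10 of lane 2 (0.374%) as doublets. Doublets were kept, and their removal was an alternative.

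No annotation of the cells was used. Counts of both lanes were log-normalized and clustered together in scanpy without batch integration, on 20 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9, seed 0). Clustering used 65 marker genes and a random 868 of the 2000 variable genes requested, chosen so that no gene of a result list took part. The remaining 14243 genes took no part in the clustering, were not markers and were the only genes compared. A cluster was named from markers when at least 3 of them were raised over 1.5-fold (with 10 CPM, UMIs scaled to a common total, added) and no other class had more of its markers among the 10 leading genes. Compared genes could take places among these 10, where only markers were counted, so they were not fully apart from the naming. The markers were fixed beforehand and this scoring was chosen after the data were seen. Among 15 clusters, 4 were progenitor-like, 2 neurogenic-like, 5 retinal ganglion cell-like, 2 amacrine/horizontal-like and 1 photoreceptor-like, and 1 stayed unnamed. One cell with 69.1% of its UMIs from erythroid markers was set aside.

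With 1 pooled sample there is no replicate and no test. The tests planned before the data were examined (edgeR and DESeq2 across libraries, set tests of gene lists, and Fisher's exact test of class shares) need cells tied to samples and are not used here; results of these tests with the lanes taken as replicates had been seen when they were set aside. Counts were summed per class over all cells and scaled to CPM with TMM factors of edgeR 4.0.16 under R 4.3.3, which lay between 0.914 and 1.082. Classes were compared in pairs by the log2 ratio of their CPM for genes with at least 10 UMIs in the classes compared. Shares of cells carry exact Clopper-Pearson intervals, CPM exact Poisson intervals and ratios exact conditional intervals, all at 95% and all covering counting error only. The ratio of 2 shares of genes carries a 95% interval from a normal approximation on the log scale. A share of 0 is given with the limit of 3 counts over the cells of the class, and it limits cells with a UMI. For ratios, a count of 0 was put at a floor of 3 counts over the class and its ratio is a bound; no ratio was formed where both counts were at or under the floor.

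The 16 gene lists were fixed before the data were examined: axon guidance receptors, axon guidance ligands, axonal adhesion molecules, axon growth and neuronal cytoskeleton, S phase, G2/M phase, Notch pathway, neurogenic transcription factors, ganglion cell subtype transcription factors, neurotransmitter transport and synthesis, synaptic vesicle release, phototransduction, immediate early and heat shock, ipsilateral ganglion cells, contralateral ganglion cells, and cell cycle inhibitors. A list with at least 3 measured members is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The interval of a median is the central 95% of 1000 draws in which each count took its counting error. A percentile describes these libraries only.

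Genes were named by size, a rule chosen after the data were seen in place of one based on p-values. Per comparison it takes the 8 largest log2 ratios each way among genes with the same direction in both lanes and at least 50 CPM in the higher class, and up to 4 members of each list with the largest ratio in size under the same conditions. Between gates it takes the 5 largest each way with at least 20 UMIs in the higher gate, and all measured ipsilateral and contralateral genes. Between lanes it takes the 5 genes differing most each way with at least 200 UMIs. The text names a part of these genes, and some that met the rule are not reported here. The 10-UMI filter and the summing of amacrine/horizontal-like and photoreceptor-like counts as "other neurons" were also chosen after the data were seen. Zic2 and Isl2 gates within ganglion cell-like cells used at least 1 Zic2 UMI, and at least 1 Isl2 UMI without Zic2. Gene positions come from GENCODE M21 on GRCm38, the assembly also called mm10, where 198 of 200 named genes had 1 location.

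Counts were simulated with Poisson error only for the neurogenic-like and progenitor-like comparison (11482 genes). The interval held the true ratio for 96.13% of 11282 unchanged genes, 94.0% of 100 genes at log2 1 in size and 98.0% of 100 genes at log2 2 in size. The intervals assume this same error, so these shares check their calculation only. They do not cover spread between cells or lanes, the clustering or the TMM scaling. A simulated list of 30 genes at log2 1 had a median of 0.88 at percentile 100, and an unchanged list a median of 0.01 at percentile 63.47. Alternatives fixed before the data were examined were size factors of DESeq2 1.42.0, no filter on low counts, Leiden resolutions 0.6 and 1.5, the remaining variable genes, doublets left out, a cell filter, thinning of each cell to 2000 UMIs, and single lanes. Further ones, chosen after the data were seen, left out genes or clusters that differed between lanes and a mitotic neurogenic-like cluster, which was recognized from leading genes that are also compared. Thinning kept 4694 cells and left out 653.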

Results

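Single-cell transcriptomes of the embryonic mouse retina were collected at E15.5, a stage at which progenitors still divide while ganglion cells, cones, amacrine and horizontal cells are being born. The cells come from 2 libraries of 1 wild-type group and are named by 2 lanes. No label ties a lane to a library, so all cells were used as 1 pooled sample. Lane 1 had a median of 3624 UMIs and 1574 genes per cell (range 1096 to 19394 UMIs), and lane 2 a median of 3847 UMIs and 1787.5 genes (1212 to 20298 UMIs). Mitochondrial genes gave a median of 2.996% of UMIs per cell in lane 1 and 2.798% in lane 2. All comparisons are between cell classes within this sample. The differences have no replicate check and were not tested; bracketed ranges are 95% intervals for counting error only.

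Progenitor-like cells, named from genes such as Sox2 and Fgf15, made up 35.98% of 5347 cells (34.7 to 37.3%). Ganglion cell-like cells, the retina's projection neurons, made up 23.5% (22.4 to 24.7%), amacrine/horizontal-like cells 14.9% (13.96 to 15.9%), neurogenic-like cells (Atoh7, Neurog2, Hes6) 14.7% (13.8 to 15.7%), and photoreceptor-like cells 7.95% (7.24 to 8.71%). The remaining 2.92% (2.48 to 3.404%) stayed unnamed, apart from 1 erythroid cell. The cells had been sorted before loading, which can set these shares. Ganglion cell-like cells were 684 of 2673 cells in lane 1 and 574 of 2674 in lane 2 (25.6% and 21.5%). Progenitor-like cells were 34.0% of lane 1 and 37.96% of lane 2. Ganglion cell-like cells were the deepest class, with a median of 8018 UMIs, against 2452 in photoreceptor-like cells. Among progenitor-like clusters, 1 drew 321 cells from lane 1 and 94 from lane 2, and another 10 and 363.

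**Figure D1:**
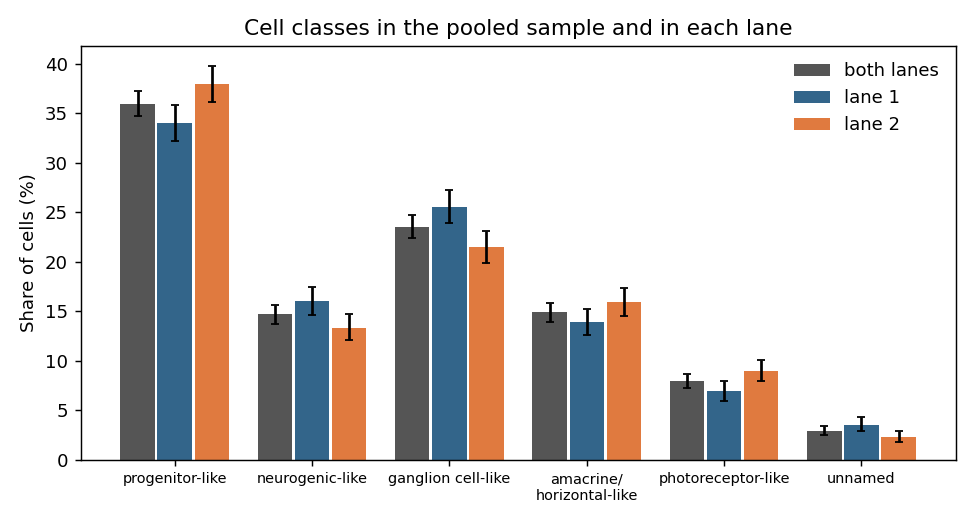
Share of cells (%) in each class over both lanes (grey) and in lane 1 and lane 2 alone; error bars are exact 95% binomial intervals, which cover counting error only. Progenitor-like cells take 34.0% of lane 1 and 37.96% of lane 2, and ganglion cell-like cells 25.6% and 21.5%.

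The first comparison addresses entry into neurogenesis. Cells on this path stop dividing, and proneural factors and Notch signalling act at the step. Neurogenic-like cells expressed Neurod4, a proneural transcription factor, at 129.7 CPM (117 to 144) against 2.13 (1.215 to 3.45) in progenitor-like cells, a log2 ratio of 5.93 (5.21 to 6.75). The homeobox gene Dlx1 had a log2 ratio of 5.80 (5.16 to 6.53), the Notch ligand gene Dll4 (chromosome 2, 119325784 to 119335962, plus strand) 5.13 (4.29 to 6.12), and the protocadherin gene Pcdh17 5.03 (4.71 to 5.37). The glutamate transporter gene Slc1a3 was lower, at 17.0 against 291 CPM (-4.10, -4.54 to -3.68). The retinoic acid-synthesizing enzyme gene Aldh1a3 (-3.77, -4.32 to -3.28) and the matrix gene Sparc (-3.65, -3.98 to -3.33) were lower as well. Hes1, a Notch effector that restrains differentiation, stood at 103 CPM against 877 CPM in progenitor-like cells (-3.09, -3.27 to -2.92). Its progenitor-like level was 1264 CPM in lane 1 and 552 CPM in lane 2.

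Neurogenic transcription factors, the list this comparison turns on, had a median log2 ratio of 1.72 (1.66 to 2.14) over 22 members, at percentile 100 of random lists; Onecut2 was among the largest (3.15, 2.78 to 3.53). The Notch pathway list had a median of 0.76 (0.42 to 1.05) over 21 members at percentile 100, with Mfng (2.97) and Rbpj (1.72) higher alongside Dll4. S phase genes were lower, with a median of -0.63 (-0.70 to -0.58) at percentile 0, and Gins2 at -1.94 (-2.26 to -1.64). G2/M genes had a median of 0.38 (0.33 to 0.42) at percentile 100, and Hmmr stood at 314 against 144 CPM (1.12, 0.99 to 1.25). The neurogenic-like class was mixed, however: 436 of its 786 cells lay in a cluster with mitotic genes among its leading genes. In the other 350 cells the medians were -1.95 for G2/M and -2.65 for S phase genes, with Hmmr at -1.83 and Gins2 at -3.32. Leaving out the 2 progenitor-like clusters drawn mostly from 1 lane instead gave G2/M genes a median of 1.29 and Hmmr 2.61. The cluster with 321 cells from lane 1 had mitotic genes such as Cenpf and Nusap1 among its leading genes. The cluster with 363 cells from lane 2 had cell cycle and histone genes such as Fbxo5 and Hist1h1b among its own. When genes differing between lanes were kept out of the clustering, a progenitor-like cluster led by Prc1 and Nusap1 drew 279 and 300 cells from the lanes. Leaving out the 2 clusters thus also took dividing cells out of the reference, and the rise cannot be read as an effect of the lanes. Cytoskeletal genes of axon growth had a median of 0.50 (0.39 to 0.70), led by the neuronal tubulin gene Tubb3 at 2297 against 199.9 CPM (3.52, 3.44 to 3.60) and the collapsin response mediator gene Dpysl3 (2.70). Synaptic vesicle genes had a median of 0.61 (0.99 without the mitotic cluster), with Cplx2 at 2.73 (2.43 to 3.03), and both lists lay at percentile 100. Immediate early and heat shock genes were lower (median -1.49, -2.07 to -1.24, percentile 0), with Fos at 270.4 against 1723 CPM and Egr1 at a log2 ratio of -2.74.

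Axon guidance receptors had a median of -0.51 (-0.80 to -0.21) at percentile 1.03, but of 0.31 without the mitotic cluster. Epha3 (1.47, or 0.78 without it) and Robo2 (0.59, or 1.05) were among the higher ones. Guidance ligands had a median of -0.43 (percentile 13.14; -0.42 in lane 1 and -1.01 in lane 2) and Efna5 a log2 ratio of -0.38. Adhesion genes had a median of -0.33 and a mean of 0.18, which differ in sign, at percentile 4.09, and Nrcam stood at -1.46. Ganglion cell subtype transcription factors (median 0.74, percentile 99.99), including Klf7 (1.94), and cell cycle inhibitors (median 0.44, percentile 99.39), including Cdkn1a (1.91), were higher, but the inhibitors had a median of -0.84 without the mitotic cluster. The few ipsilateral genes had a median of -1.84 over 4 members (percentile 0.12) and the contralateral genes -0.66 over 4 (percentile 18.36), which were -0.83 and 0.16 without that cluster. Phototransduction genes lay at percentile 73.1. Neurotransmitter genes, at percentile 93.22, had a median of 0.32 (0.49 in lane 1 and -0.34 in lane 2) and a mean of -0.24. Gad2 had a log2 ratio of 0.38 (0.08 to 0.67), which was -0.16 at Leiden resolution 0.6 and 0.92 without the mitotic cluster. Leaving that cluster out took 4 of 16 list medians and 36 of 61 named genes of this comparison out of their intervals, and 3 and 5 more changed sign. Across 11500 genes, which are not independent replicates, the log2 ratios of the lanes had a Pearson r of 0.668.

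**Figure D2:**
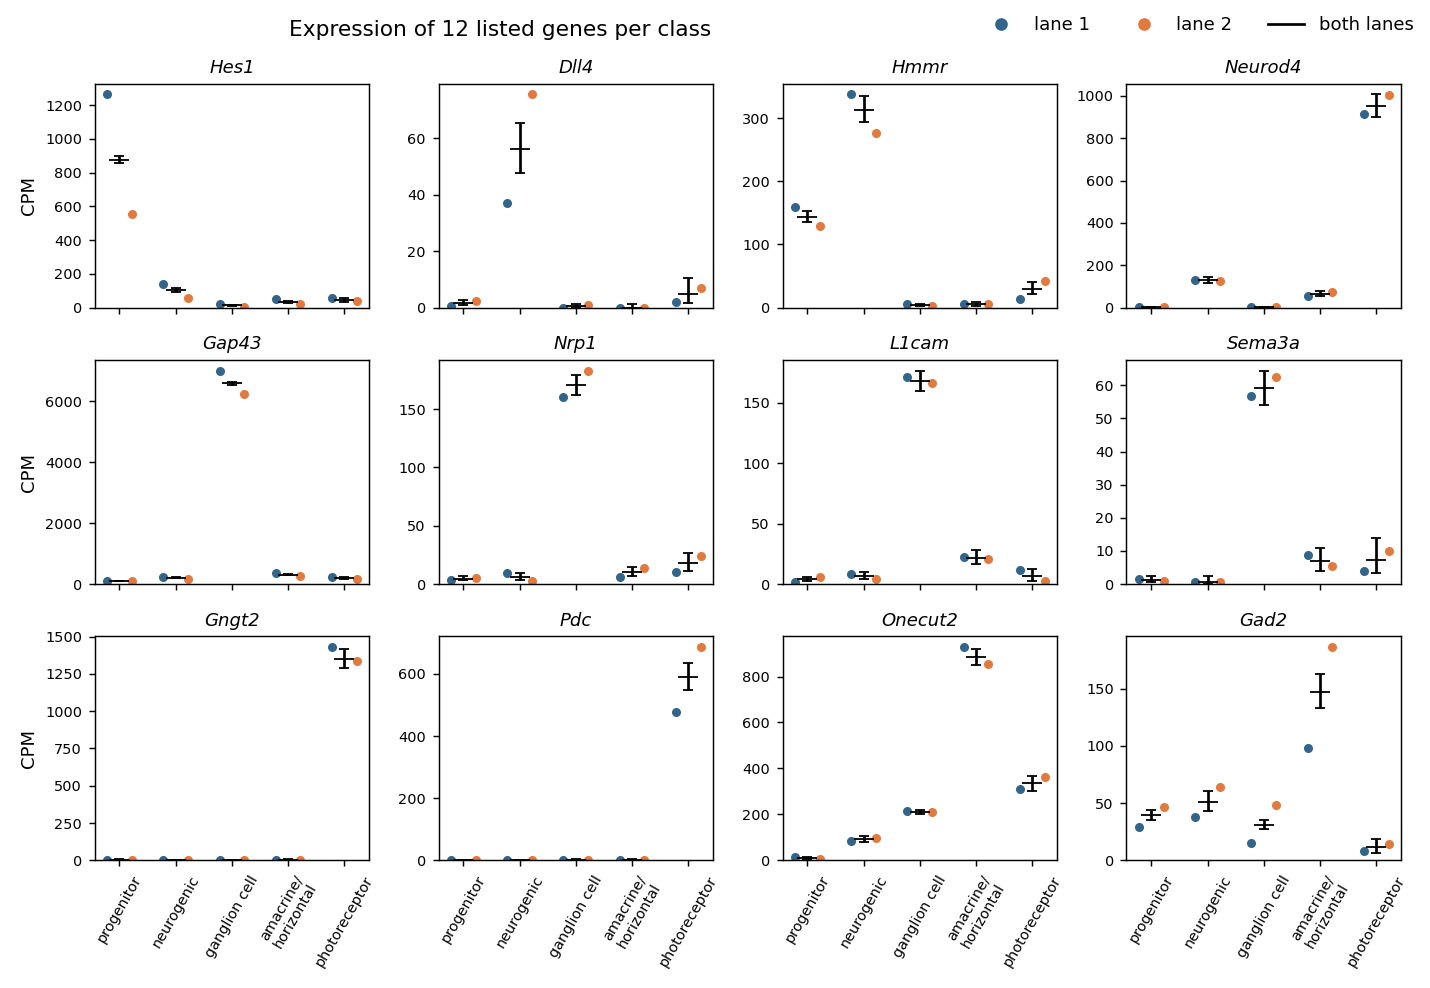
TMM-scaled CPM (linear axes from 0) of 12 listed genes in 5 cell classes; black dashes with bars are both lanes with exact 95% Poisson intervals, and dots are lane 1 and lane 2. Gap43 reaches 6590 CPM in ganglion cell-like cells, Gngt2 1351 CPM in photoreceptor-like cells and Hmmr 314 CPM in neurogenic-like cells.

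Differentiation of ganglion cells was measured against neurogenic-like cells. Ganglion cells send axons to the brain, and their genes for growth cones, guidance and adhesion were the question here. Gap43, which encodes a growth cone protein (chromosome 16, 42248442 to 42340651, minus strand) and is named here after its values were seen, stood at 6590 CPM (6537 to 6644) in ganglion cell-like cells and 204 CPM (187 to 221) in neurogenic-like cells. The receptor gene Nrp1 (chromosome 8, 128358604 to 128503363, plus strand), which binds class 3 semaphorins, had 170.4 against 6.02 CPM, a log2 ratio of 4.82 (4.14 to 5.61). The cell adhesion gene L1cam (chromosome X, 73853778 to 73896105, minus strand) had 168 against 6.38 CPM (4.72, 4.05 to 5.48). Sema3a, a secreted guidance cue (chromosome 5, 13125414 to 13602565, plus strand), had 521 UMIs in ganglion cell-like and 2 in neurogenic-like cells, an 83.4-fold ratio (23.0 to 691). By the same measure Igf1 was 178-fold higher (60.7 to 863), the somatostatin gene Sst 202-fold (36.1 to 7990) and the vesicular glutamate transporter gene Slc17a6 101-fold (27.9 to 839). Dll4 (-6.95, -8.84 to -5.56), Hmmr (-6.34), the topoisomerase gene Top2a (-6.16) and the Notch effector Hes5 (-6.05) were lower. Without the mitotic cluster the log2 ratio was 4.76 for Sst, -3.39 for Hmmr and -2.61 for Top2a.

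Guidance receptors had a median log2 ratio of 0.73 (0.39 to 1.05) over 30 members, at percentile 98.52, with Robo2 higher (1.15, or 0.69 without the mitotic cluster) and Epha3 lower (-5.81, -6.83 to -4.93). Guidance ligands had a median of 1.67 (1.28 to 1.86) over 28 members at percentile 100, including Sema6a (2.17). In single lanes, over the members each lane measured, the ligand median was 1.32 and 1.17, and it was 1.05 without the mitotic neurogenic-like cluster. Cytoskeletal genes had a median of 2.61 (2.50 to 2.74), with Ina at 6.00 (5.58 to 6.44), Mapt at 5.57, Dcx at 5.50 and Tubb2a at 5.26. Synaptic vesicle genes had a median of 2.99 (2.54 to 3.20), with Syt4 at 5.30, and adhesion genes 1.82 (1.47 to 1.99), with Cntn2 at 3.90 (3.28 to 4.60); these 3 lists lay at percentile 100. Ganglion cell subtype factors had a median of 1.35 (0.92 to 1.86) at percentile 99.99 (0.71 without the mitotic cluster), including Ebf1 at 1650 against 70.5 CPM (4.55, 4.35 to 4.76) and Ebf3 (3.36). Contralateral genes had a median of 3.60 over 4 members (2.95 to 4.42, percentile 99.94), among them Fgf12 (5.24) and Nrcam (1.30, or 1.96 without that cluster). Ipsilateral genes had a median of 1.06 (0.81 to 1.31, percentile 86.89), which was 0.53 in lane 1, 0.65 in lane 2 and -0.08 once the mitotic cluster was left out.

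Cell cycle genes were lower, with medians of -3.05 (-3.16 to -2.78) for S phase and -4.92 (-5.10 to -4.75) for G2/M genes, including Rrm2 (-5.61) and Nusap1 (-6.22). Without the mitotic cluster these 4 values were -1.0, -2.19, -2.97 and -2.79. Notch pathway genes had a median of -2.07 (-2.54 to -1.96), and Notch1 stood at 5.11 against 256 CPM (-5.65, -6.12 to -5.21). All 3 of these lists were at percentile 0. Neurogenic factors divided, with Myt1l higher (6.32, 5.09 to 7.95) and Neurod4 lower (-5.35, -5.96 to -4.80), and their median of 0.64 and mean of -0.36 differ in sign (percentile 98.86). Immediate early and heat shock genes had a median of -0.26 (percentile 10.24), phototransduction genes 0.49 (percentile 75.36) and cell cycle inhibitors -0.17 (percentile 32.23; 0.16 in lane 1, 0.08 in lane 2 and 0.74 without the mitotic cluster). Neurotransmitter genes had a median of 2.3 (1.69 to 2.67, percentile 99.92) over 9 members, 5 of them higher and 4 lower in both lanes. It was 1.22 in lane 1 and 0.94 in lane 2, over the members each lane measured, 0.99 without the mitotic cluster and -0.32 without the filter on low counts. Gad2 was lower (-0.73, or -1.27 without the mitotic cluster), though its log2 ratio was 0.07 when genes differing between lanes were kept out of the clustering. Leaving out the mitotic cluster, 436 of the 786 cells of the reference, took 8 of 16 list medians and 32 of 65 named genes out of their intervals, and 1 and 2 more changed sign. The log2 ratios of the lanes had a Pearson r of 0.874 across 11929 genes.

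Photoreceptor-like cells were set against neurogenic-like cells in the same way. At this stage the photoreceptors being born are largely cones, and genes of the cone light response were among the largest differences. Gngt2, the gene for a cone transducin subunit (chromosome 11, 95837216 to 95845734, plus strand), reached 1351 CPM (1287 to 1418) against 1.42 (0.386 to 3.63), a log2 ratio of 9.90 (8.54 to 11.77). Phosducin (Pdc; chromosome 1, 150319417 to 150333906, plus strand) was 832-fold higher (229 to 6880), the cone channel subunit gene Cngb3 679-fold (121 to 26900) and the cone transducin gene Gnat2 430-fold (76.3 to 17100), each against 1 or 2 UMIs. Neurod4 was higher still than in neurogenic-like cells, at 952 against 129.7 CPM (2.88, 2.71 to 3.05; 1.78 without the mitotic cluster), while Dlx1 (-5.20, -6.83 to -3.96), Hes5 (-4.63) and Sox11 (-2.69) were lower.

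Phototransduction genes had a median log2 ratio of 5.49 (4.73 to 5.69) over 14 members, at percentile 100. Their median was 4.50 in lane 1 and 4.66 in lane 2, over the members each lane measured, 3.97 without the mitotic cluster and 4.23 in thinned cells. Within each such part of the data a reference count of 0 was put at 3 counts. This lowers the ratios of genes with few reference UMIs, such as Cngb3 and Gnat2. A part of these drops can come from the floor, which was not tested. Synaptic vesicle genes had a median of 1.24 (1.10 to 1.80, percentile 100), led by Cplx3 (6.11, 5.21 to 7.18) and the chromogranin gene Chgb (5.83). Neurotransmitter genes had a median of 1.78 (1.2 to 2.15, percentile 99.98; 1.01 in lane 1 and 1.39 in lane 2), with the glutamate transporter genes Slc17a6 and Slc1a2 (3.31, 2.90 to 3.73) higher and Gad2, which encodes a GABA-synthesizing enzyme, lower (-2.18, -3.09 to -1.39). S phase genes (median -1.99, -2.15 to -1.83), G2/M genes (-3.18, -3.28 to -2.98), Notch pathway genes (-1.31, -1.72 to -0.96) and neurogenic factors (-1.24, -1.96 to -0.81) were at percentile 0. Among them were Rrm2 (-3.99), Nusap1 (-4.12), Notch1 (-1.98) and Rbpj (-1.89). Without the mitotic cluster the medians were 0.08 for S phase, -0.67 for G2/M and -0.68 for neurogenic factor genes, with Rrm2 at -1.35 and Nusap1 at -0.69. That alternative took 7 of 14 list medians and 27 of 59 named genes out of their intervals, and 1 and 4 more changed sign.

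Guidance genes were near the level of random lists in photoreceptor-like cells, with medians of 0.08 for receptors (-0.21 to 0.51, percentile 64.7) and 0.11 for ligands (-0.33 to 0.55, percentile 60.38). In single lanes these were -0.28 and 0.42 for receptors, and 0.27 and -0.08 for ligands. The Slit receptor gene Robo2 nonetheless stood at 523 against 93.2 CPM (2.49, 2.28 to 2.70) and the ligand gene Slit2 at 54.3 against 20.55 CPM (1.40, 0.87 to 1.93). Adhesion genes had a median of -0.17 (percentile 31.98), with Cntn1 at 5.68 (4.98 to 6.47) and Pcdh17 at -2.94. Cytoskeletal genes had a median of 0.03 (percentile 97.73; -0.14 without the mitotic cluster), with Dcx at 3.13 (2.50 to 3.79). Subtype factors (median 0.02, -0.12 in lane 1 and 0.14 in lane 2, percentile 58.15), contralateral genes (0.29 over 3 members, percentile 74.99) and cell cycle inhibitors (median -0.30, mean 0.01, percentile 30.88; median 0.86 without the mitotic cluster) were within the range of random lists. Immediate early and heat shock genes had a median of 0.35 (0.12 to 0.57, percentile 97.18), but -0.19 in lane 1, 1.01 in lane 2 and 1.21 without that cluster. The lanes' log2 ratios had a Pearson r of 0.703 across 10084 genes.

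Amacrine and horizontal cells are the inhibitory interneurons of the retina, and their comparison with neurogenic-like cells concerns interneuron differentiation. The class expressed the zinc finger gene St18 at 205 CPM (188 to 223) against 2.48 (0.997 to 5.11), a log2 ratio of 6.37 (5.31 to 7.69). Onecut2, a transcription factor of horizontal and other early-born cells (chromosome 18, 64340020 to 64400987, plus strand), stood at 885 against 93.2 CPM (3.25, 3.06 to 3.44). The stress-response gene Nupr1 had 245 against 3.90 CPM (5.97, 5.13 to 6.98). Of the cell cycle inhibitors, Cdkn1c was higher (3.35, 3.02 to 3.70) and Cdkn1a lower (-4.67, -6.14 to -3.52). Pmfbp1 had no UMI in neurogenic-like cells and was at least 77.1-fold higher, the scaffold gene Dlg2 was 122-fold higher (33.3 to 1010) and the semaphorin receptor gene Plxna2 90.6-fold (30.7 to 442). No Dll4 UMI was found among 2594187 UMIs of these cells, against 158 in neurogenic-like cells, at least 49.4-fold lower.

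Neurotransmitter genes had a median log2 ratio of 1.53 (1.38 to 1.88) over 8 members, at percentile 99.96. Gad2 stood at 147 against 51.4 CPM (1.52, 1.24 to 1.80; 0.98 without the mitotic cluster) and the GABA transaminase gene Abat at 161 against 55.3 CPM (1.54, 1.28 to 1.82). Slc1a2 was higher as well (1.37, 0.93 to 1.82), but its log2 ratio was -0.27 at Leiden resolution 0.6, -0.17 at 1.5 and 0.76 without the mitotic cluster. Guidance ligands had a median of 1.34 (0.99 to 1.73), with Slit2 at 2.16 and Efna5 at 1.77. Cytoskeletal genes had 1.03 (0.98 to 1.15), with Dcx at 3.80 and Ina at 3.73, and synaptic vesicle genes 1.61 (1.29 to 1.92), with Chgb at 4.65 and Syt1 at 2.13. These 3 lists were at percentile 100. Adhesion genes had a median of 0.79 (0.38 to 0.96, percentile 99.99), including Flrt3 (2.71), and receptors 0.39 (0.10 to 0.60, percentile 94.77), a median of -0.02 in lane 1 and 0.23 in lane 2. S phase genes (-2.47, -2.67 to -2.28) and G2/M genes (-4.84, -4.87 to -4.40) were at percentile 0, with Cenpf at -5.82 and Plk1 at -5.75. Without the mitotic cluster these 4 values were -0.45, -1.80, -3.26 and -2.22.

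Notch pathway genes were lower in amacrine/horizontal-like cells (median -0.91, -1.57 to -0.74, percentile 0.01), with Notch1 at -2.35. Neurogenic factors had a median of -0.02 and a mean of 0.49, which differ in sign, at percentile 51.98, and Nhlh2 was among the higher ones (4.62, 3.94 to 5.39). Immediate early and heat shock genes had a median of -0.40 (percentile 3.87) and cell cycle inhibitors -0.48 (percentile 3.9), which were -0.15 and 1.04 without the mitotic cluster. That alternative took 5 of 15 list medians and 36 of 63 named genes out of their intervals, and 1 of each changed sign. Subtype factors (0.16, percentile 72.59; -0.09 in lane 1 and 0.21 in lane 2), phototransduction genes (0.29, percentile 78.56), ipsilateral genes (0.68 over 3 members, percentile 84.19) and contralateral genes (1.51 over 3, percentile 97.28) had medians above 0. Across 10604 genes the lanes' log2 ratios had a Pearson r of 0.787.

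To ask what separates projection neurons from other young neurons, ganglion cell-like cells were compared with photoreceptor-like and amacrine/horizontal-like cells added up. Only ganglion cells extend a long axon out of the eye. Gap43 stood at 6590 against 272 CPM, a log2 ratio of 4.60 (4.51 to 4.69), the microtubule gene Mapt at 1092 against 87.9 CPM (3.64, 3.48 to 3.80) and the sodium channel gene Scn9a at 262 against 4.12 CPM (5.99, 5.29 to 6.80). Nrp1 had 170.4 against 12.6 CPM (3.75, 3.34 to 4.20) and Sema3a 59.1 against 6.96 CPM (3.09, 2.53 to 3.70). The transcription factor genes Ebf1 (4.08) and Ebf3 (4.91) were higher. Gngt2 (-7.37), Neurod4 (-6.78, -7.37 to -6.24), the fatty acid-binding protein gene Fabp7 (-6.60) and Slc1a2 (-3.43) were lower. The reference includes photoreceptor-like cells, in which Gngt2, Neurod4 and Slc1a2 were higher than in neurogenic-like cells.

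Cytoskeletal genes had a median log2 ratio of 1.54 (1.5 to 1.62) over 32 members, at percentile 100. Guidance receptors lay at percentile 28.97 with a median of -0.08 and a mean of 0.26, which differ in sign, and Plxna2 (-3.65) and Dcc (-1.12) were among the lower ones. Guidance ligands had a median of 0.47 (0.22 to 0.67, percentile 98.43), with Sema6a higher (1.69) and Efna5 lower (-1.30). Adhesion genes had a median of 0.64 (0.56 to 0.89, percentile 99.98), among them Cntn2 (4.76, 4.05 to 5.57) and L1cam (3.32). Subtype factors (0.88, 0.62 to 1.19) and synaptic vesicle genes (1.12, 0.94 to 1.28) were at percentile 100, the latter with Syt4 at 5.26 and Cplx3 at -5.48. Contralateral genes had a median of 2.71 (2.38 to 3.09, percentile 99.98), with Igf1 at 6.52 (5.54 to 7.73) and Fgf12 at 3.70. Ipsilateral genes had a median of 0.27 (percentile 69.84), but -0.36 in lane 1, -0.07 in lane 2 and -1.94 in thinned cells.

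Phototransduction genes were lower in ganglion cell-like cells (median -5.27, -5.99 to -4.23), as were S phase (-0.68, -0.74 to -0.47) and G2/M genes (-0.90, -1.01 to -0.74), all at percentile 0. Rangap1 was an exception among the G2/M genes (1.41, 1.22 to 1.60). The phototransduction value is against a sum that includes photoreceptor-like cells. Against neurogenic-like cells that list had medians of 0.49 in ganglion cell-like and 0.29 in amacrine/horizontal-like cells. Notch pathway genes had a median of -0.79 (percentile 0.04), with Notch1 at -3.43, and neurogenic factors -0.43 (percentile 0.14), with St18 at -5.36. Neurotransmitter genes were split, with 5 members higher and 6 lower in both lanes, the latter including Abat (-2.18) and Gad2 (-1.75). Their median was -1.75 (-1.92 to -1.33, percentile 0) over 11 members and their mean -0.53. The median was 0.61 in lane 1 and -1.45 in lane 2 over the members each lane measured, so it gives no direction for the list. Immediate early and heat shock genes had a median of -0.50 (percentile 0.59) and cell cycle inhibitors -0.22 (percentile 15.02; -0.01 in lane 1, -0.23 in lane 2 and 0.04 in thinned cells), of which Cdkn1a was higher (2.09) and Cdkn1c lower (-1.24). Across 12047 genes the lanes' log2 ratios had a Pearson r of 0.804.

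The last comparison concerns the choice of midline crossing, for which Zic2 is known to mark ganglion cells with ipsilateral axons and Isl2 those with contralateral ones. Zic2 (chromosome 14, 122475435 to 122479852, plus strand) had a UMI in 12 of 1258 ganglion cell-like cells (0.954%, 0.494 to 1.66%) at a median depth of 8018 UMIs. In progenitor-like cells, at a median of 3680.5 UMIs, the share was 17 of 1924 (0.884%), and after thinning to 2000 UMIs the shares were 0.482% and 0.475%. Thinned, the lanes ran opposite ways, with 0.297% in ganglion cell-like and 0.780% in progenitor-like cells in lane 1. In lane 2 these shares were 0.7005% and 0.219%. The pooled ganglion cell-like share therefore could not be told from the progenitor-like share at this depth. No background of free RNA was measured, so neither share is known to be background. Amacrine/horizontal-like cells had a share of 28 of 797 (3.51%, 2.35 to 5.04%). After thinning it was 1.96% (1.08 to 3.27%) against 0.475% (0.205 to 0.9345%) in progenitor-like cells. Neurogenic-like cells, at a median of 3575 UMIs, had 21 of 786 (2.67%, 1.66 to 4.06%), but 1.13% thinned (0.491 to 2.22%), which overlaps the progenitor-like interval. In lane 1 the thinned shares were 0.545% in neurogenic-like and 0.780% in progenitor-like cells. In lane 2 they were 1.775% and 0.219%, so the lanes disagreed in direction. Isl2 (chromosome 9, 55538672 to 55546180, plus strand) had a UMI in 62 ganglion cell-like cells (4.93%, 3.80 to 6.27%; 1.21% thinned) and in 0 of 1924 progenitor-like cells, which at the limit of 3 counts allows a share of cells with a UMI of up to 0.156%. Photoreceptor-like cells, at a median of 2452 UMIs, had Isl2 in 10 of 425 (2.35%, with 1.62% in lane 1 and 2.92% in lane 2). Thinned, the share was 1.60%, and all of these cells came from lane 2 (2.69% of its cells).

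The gates held 12 Zic2 and 61 Isl2 ganglion cell-like cells, 3 and 27 of them in lane 1 and 9 and 34 in lane 2, with 72534 and 560809 UMIs. Mstn, a growth factor gene, had 1 UMI in the Zic2 gate and 176 in the Isl2 gate, a 27-fold ratio (4.79 to 1070). Mstn was also a leading gene of 1 ganglion cell-like cluster of 302 cells. The ratio can therefore reflect which clusters the few gated cells came from, which was not tested. Cells of the Isl2 gate also held more UMIs each on average, and a gate on at least 1 UMI can favour deep cells. This limit applies to all values between the gates. The ipsilateral gene Ephb1 had 4 and 10 UMIs (log2 ratio 1.38, -0.75 to 3.17). Of the contralateral genes, Igf1 had a log2 ratio of -1.24 (-3.57 to 0.40), Fgf12 -0.22 (-1.93 to 1.12) and Nrcam -0.03 (-1.56 to 1.21), so no difference was detectable in these 4 genes at this depth. The contralateral median was -0.22 (-1.54 to 0.56, percentile 40.76), and the ipsilateral list had under 3 measured members and no median. Cytoskeletal genes had a median of -0.49 (-0.61 to -0.38, percentile 0) over 31 members, but -1.34 in lane 1, with 3 Zic2 cells, and -0.44 in lane 2. Guidance receptors had a median of 0.29 (0.02 to 0.90, percentile 85.29), but -0.11 in lane 1 and -0.84 with gates set on thinned cells. The pooled median was set by the floor. It was the value of Plxna3, with 0 UMIs in the Zic2 gate, put at 3 counts, and 16 in the Isl2 gate. Plxnb1 (0 and 14 UMIs) and Plxnb2 (0 and 10) counted as higher by the same bound. The pooled median therefore gives no direction for this list. Medians of other lists between gates, and those of single lanes, can carry the same limit. Median and mean differed in sign for adhesion genes (-0.03 and 0.08; lane medians 0.45 and 0.13) and for immediate early and heat shock genes (0.31 and -0.01). The percentiles of the remaining lists ranged from 2.77 (phototransduction genes, 3 members) to 97.18 (immediate early and heat shock genes). Across 5967 genes the log2 ratios of the lanes had a Pearson r of 0.156.

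The lanes themselves differed in a set of genes. Of 8363 genes with at least 200 UMIs, 830 differed over 2-fold in CPM, 811 of them lower and 19 higher in lane 1. Over 4-fold, 309 were lower and 2 higher in lane 1. The 811 genes gave 2.05% of lane 1 UMIs and 8.32% of lane 2 UMIs. The linker histone gene Hist1h1e had 64 UMIs in lane 1 and 3388 in lane 2. Gm10126 (437 and 67 UMIs), Gm10263 (685 and 166), Gm10076 (5631 and 1659), Tsix (462 and 171) and B930036N10Rik (191 and 76) had the largest differences the other way. GENCODE M21 lists none of them as protein-coding: Gm10126 and Gm10263 are processed pseudogenes, Gm10076 a lincRNA gene, and Tsix and B930036N10Rik antisense genes. The globin genes Hba-a2 (0 and 2307 UMIs), Hba-a1 (5 and 2676), Hbb-bs (7 and 3352) and Hbb-bt (4 and 1992) led the differences, most of their UMIs coming from 1 erythroid cell of lane 2. These are values without a test.

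**Figure D3:**
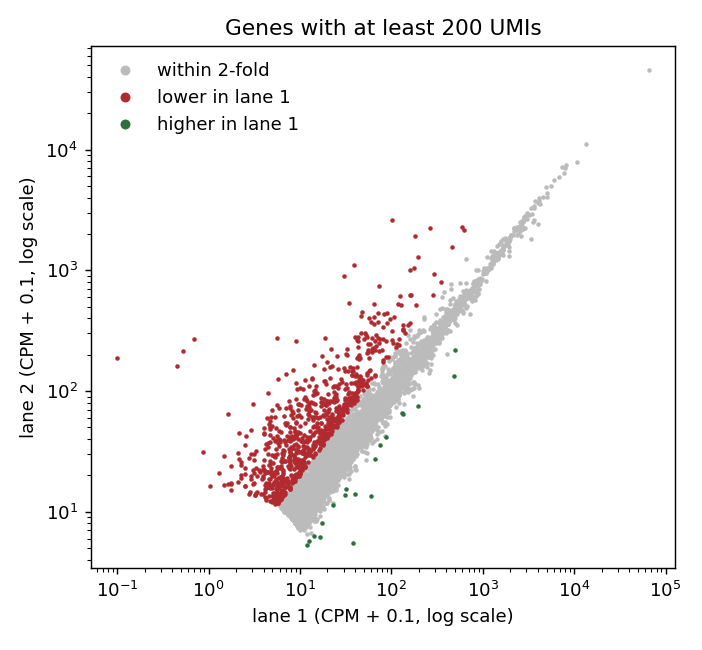
CPM plus 0.1 of 8363 genes with at least 200 UMIs in lane 1 and lane 2, both axes on a log scale; each point is a gene. The 811 points above the diagonal by over 2-fold are lower in lane 1, and 19 are higher.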

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

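Among the tests below, those of low depth and of overlapping exons were chosen after other results on the same pattern had been seen. The test of low depth, bounds included, replaced an earlier form that left cluster 1 out and whose result had been seen. Chosen late as well were the check of the ganglion cell test on other profiles and the intervals of shares and ratios that decide on shared sequence, overlapping exons and mitochondrial loss, and the weighing of all 3 patterns followed their discovery in these data. The set of ganglion cell genes used for the unnamed cluster was chosen again, by size, after an earlier form of its test had been seen. The design holds 1 group, so no biological explanation was tested for any of them.

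A signal lay outside the classes compared in 2 places. One cell of lane 2, with 14804 UMIs, had 69.1% of its UMIs from erythroid marker genes, chiefly globins, and was set aside. The 156 cells of the unnamed cluster had a median of 18.5% of UMIs from mitochondrial genes, at a median depth of 1483.5 UMIs, and took part in no comparison.

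The unnamed cluster was weighed first. It was compared over 1250 genes over 2-fold higher in ganglion cell-like cells than in other neurons in both lanes. For the ratios and correlations of this paragraph, 10 CPM was added to each profile before the log. This pulls ratios of weakly expressed genes towards 0, and the 1250 genes were chosen without it. The cluster's log2 ratio to ganglion cell-like cells had a median of -0.04 as the mean of the lanes (0.10 in lane 1, -0.18 in lane 2). Across genes its profile had the highest Pearson r of 5 classes with that class (0.873 in lane 1 and 0.811 in lane 2). This does not single out damaged ganglion cells. The pooled lane had medians of -0.40 and -0.46 by the same measure, and each other class lay within 1 of 0, down to -0.94. With 10 CPM added, the bound of 1 set beforehand thus excluded none of them, and these values do not show how alike the classes are. The pooled lane 1 also correlated best with ganglion cell-like cells (0.961), while pooled lane 2 did so with neurogenic-like cells (0.957). Damaged ganglion cells stay open. The cluster's median log2 ratio to the pooled lane over the same genes was 0.44, while ganglion cell-like cells themselves lay at 0.43. The added 10 CPM pulled both values towards 0, and the pooled lane includes the ganglion cell-like cells. The bound of 0.8 set beforehand against droplets of mostly free RNA was therefore out of reach for reasons of the measure. The test says nothing about the cells, and that explanation stays open too.

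Progenitor-like cluster 1 (398 cells, 252 and 146 per lane) had a median of 0.299% mitochondrial UMIs, and 6 mitochondrial genes were among those used for clustering. Low depth is argued against as the whole cause: of all progenitor-like cells as shallow, cluster 1 included, 50.67% had at least 1% mitochondrial UMIs (mean of the lanes; 48.8%, 42.8 to 54.75%, in lane 1 and 52.6%, 45.65 to 59.45%, in lane 2). Of deeper progenitor-like cells, 27% in lane 1 and 23.7% in lane 2 had under 1%. The shallow cells had the lower medians, at 0.84% against 2.86% in lane 1 and 1.13% against 2.59% in lane 2, so a part of low depth stays open. Nuclei, or cells that lost cytoplasm, may contribute, but the median CPM ratio of nuclear-retained RNAs was 1.26 (mean of the lanes), between the bounds set beforehand. Loss of mitochondrial RNA in cells of every class, set beforehand at 5% or more of cells under 1% mitochondrial UMIs in each other class, is argued against. The lowest share was 0.64% (ganglion cell-like cells, 0.275 to 1.25%), with 1.02% in lane 1 (up to 2.097%) and 0.17% in lane 2. Lane 1 missed the opposite bound of under 1%, also set beforehand. The share was 0.753% in amacrine/horizontal-like and 1.41% in photoreceptor-like cells, against 89.95% in cluster 1. Neurogenic-like cells had 10.8% and other progenitor-like clusters 16.2%, so a loss limited to these cells stays open and was not tested.

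The genes lower in lane 1 were lower in every class, with class medians of the log2 ratio from 1.69 to 1.94, which argues against different shares of the cell classes. For shared sequence with near-identical copies, exact stretches of 50 nt were sought in other genes of GENCODE M21. They came from the last 300 nt of each gene's longest coding transcript. An end counted as shared when over 20% of its stretches occurred elsewhere. This held for 3.871% of 775 affected and 3.772% of 6151 unaffected genes, a ratio of 1.03 (0.71 to 1.49). It argues against such copies as the whole cause. Copies without such stretches, and the genes higher in lane 1, were not covered. Overlapping exons of another gene on the same strand gave a ratio of 1.06 (0.51 to 2.2), too wide to decide alone. They are argued against as the whole cause, since 8 of 775 affected genes had an overlapped end (1.032%, 0.447 to 2.02%) against 0.975% of unaffected genes. Among genes over 4-fold lower in lane 1 the share was 5 of 293 (1.706%, 0.556 to 3.94%), and a part in these few genes stays open. GC content near the 3' end was tested before the overlap and then replaced by it among the tests of this pattern. It had a Spearman rho of 0.001 with the log2 ratio across genes, which are not independent replicates. This argues against a steady trend with GC over all genes. No bound was set beforehand and affected genes were not compared with unaffected ones, so an effect limited to the affected genes stays open. No cause was found, and differences in how the libraries were made or counted were not tested.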

How the results depend on the processing

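Alternatives that left out genes or clusters differing between lanes, or the mitotic cluster, were chosen after the data were seen, and so were the lists treated as the main value of each comparison. A value is said to have moved when it left the 95% interval for counting error of the pooled value, and for every move below the cause was not tested. Over all alternatives, 21 values of class shares stayed within that interval and 19 moved. Of list medians 946 stayed, 149 moved and 16 changed sign against an interval that excluded 0. For named genes these numbers were 3648, 490 and 18. With DESeq2 size factors 332 values of named genes and 93 list medians stayed and 1 moved.

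At Leiden resolution 0.6 the ganglion cell-like share was 25.7% and the amacrine/horizontal-like share 12.4%. Guidance ligands in ganglion cell-like cells had a median of 1.87, neurotransmitter genes in amacrine/horizontal-like cells 2.03, and cytoskeletal genes against other neurons 1.48. Gad2 in neurogenic-like cells was -0.16 and Slc1a2 in amacrine/horizontal-like cells -0.27. At resolution 1.5 the neurogenic-like, ganglion cell-like and amacrine/horizontal-like shares were 18.6%, 22.2% and 12.3%, phototransduction genes in photoreceptor-like cells had a median of 5.81 and Slc1a2 was -0.17. With the remaining variable genes the neurogenic-like share was 15.8% and the amacrine/horizontal-like share 13.3%. Clustering without genes differing between lanes gave shares of 12.2% (neurogenic-like) and 25.75% (ganglion cell-like), medians of 1.59 for neurogenic factors and 1.49 for cytoskeletal genes against other neurons, and Gad2 at -0.25 in neurogenic-like and 0.07 in ganglion cell-like cells. Leaving those genes out of the comparison gave neurogenic factors a median of 1.64. Leaving out the 2 progenitor-like clusters mostly of 1 lane moved 11 of 61 named genes and 1 of 16 list medians of neurogenic-like against progenitor-like cells, G2/M genes, to 1.29. Mitotic genes were among the leading genes of 1 of these clusters, and cell cycle and histone genes such as Fbxo5 and Hist1h1b among those of the other. This alternative therefore also took dividing cells out of the reference.

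Cells thinned to 2000 UMIs gave medians of 2.18 for neurogenic factors, 4.23 for phototransduction genes, and against other neurons 1.49 for cytoskeletal, -1.94 for ipsilateral and 0.04 for cell cycle inhibitor genes. Leaving out the mitotic cluster weighed most: in the 4 comparisons with neurogenic-like cells 24 list medians and 131 named genes moved, 6 and 12 changed sign, and 31 and 105 stayed. Ganglion cell-like against neurogenic-like cells then had 1.05 for guidance ligands, -0.08 for ipsilateral genes, 0.15 for Cdkn1b and -0.07 for Hspa8. Neurogenic-like against progenitor-like cells had medians of 0.31 for guidance receptors, -1.95 for G2/M genes and -0.84 for cell cycle inhibitors, with Hmmr at -1.83, Cdkn1b at -0.66 and 3 other cell cycle genes at -1.21, -1.24 and -1.03. Photoreceptor-like cells had medians of 3.97 for phototransduction and 0.08 for S phase genes, and 4 genes lower before stood at 0.05, 1.0, 0.25 and 1.08. Amacrine/horizontal-like cells had medians of 1.3 for neurotransmitter genes and 1.04 for cell cycle inhibitors, and Cdkn1b at 0.08. Without a filter on low counts the neurotransmitter median of ganglion cell-like against neurogenic-like cells was -0.32. With gates set on thinned cells, guidance receptors had a median of -0.84 and Gria4 was 0.0.

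In single lanes the shares ranged from 34.0 to 37.96% (progenitor-like), 13.35 to 16.05% (neurogenic-like), 21.5 to 25.6% (ganglion cell-like), 13.9 to 15.9% (amacrine/horizontal-like) and 6.92 to 8.975% (photoreceptor-like). Medians ranged from 1.81 to 1.95 for neurogenic factors in neurogenic-like cells, 0.63 to 0.88 and 1.17 to 1.32 for receptors and ligands in ganglion cell-like cells, and 4.50 to 4.66 for phototransduction genes. Against other neurons they were 1.53 to 1.56 for cytoskeletal, -1.45 to 0.61 for neurotransmitter and -0.36 to -0.07 for ipsilateral genes. In amacrine/horizontal-like cells they were 1.24 to 1.88 for neurotransmitter genes and -0.02 to 0.23 for receptors, in photoreceptor-like cells -0.19 to 1.01 for immediate early genes, and between gates -0.11 to 0.16 for receptors; contralateral genes had a value of -0.44 in lane 2 alone. A single lane measures fewer members of each list.

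The planned edgeR, DESeq2 and set tests, the library block, the fold threshold on called genes and an estimated correlation are not used here, because no label ties cells to a sample. A gate of at least 2 Zic2 UMIs held no cells and gave no value. Depth limits the Zic2 comparison, with 12 cells in its gate.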
